A study of Homo sapiens with 6 samples.

How the data were processed

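Gene expression was measured by RNA-seq in 6 libraries of UWB1.289 cells, an established human ovarian carcinoma line that lacks functional BRCA1. Cells received lentiviral short hairpin RNA, either as a control (shCTRL, 3 libraries) or against HBO1 (shHBO1, 3 libraries). HBO1 is the histone acetyltransferase encoded by KAT7, also named MYST2. Per the labels' protocols, transduction was done with polybrene at 10 µg/mL, and puromycin selection at 1 to 3 µg/mL began after 96 h. Libraries were made from total RNA with a standard Illumina protocol, per the labels' protocols. Poly(A) selection, strandedness, read length and the number of hairpins are not given in the sources used here. The replicates carry the numbers 1 to 3 in each group, and nothing in the labels says that they were separate cultures. The p-values then measure only the spread between these libraries, which may be technical.

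The authors deposited 1 table of normalized signal for the whole series, with 58215 RefSeq transcript accessions (44893 protein-coding and 13322 non-coding) and 6 columns. Bowtie 1.2.1.1, SAMtools, DESeq2 and the genome build hg19 are named in the submitters' processing notes, without their roles. How reads were shared between transcripts is not given in the sources used here. Every deposited value was a whole multiple of a step specific to its library, so each was taken as a read count scaled by 1 factor per library. Dividing by the step gave whole reads for 100% of values in each library, at a tolerance of 0.01 read. The recovered totals ran from 35940400 to 39908703 reads per library. No fold-change table of the authors was used, so the planned comparison with their calls was not made.

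Gene names came from the RefSeq annotation of GRCh38.p14 for 57191 accessions and from GENCODE release 29 for 646 more. The 378 accessions without a name held 0.0920 to 0.0977% of reads and were left out. Because the build differs from hg19, no coordinates are printed. Because the assignment of reads to transcripts is unknown, the normalized counts of all transcripts of a gene were summed, which gave 26967 named genes. A read that was counted for several transcripts would enter such sums, and the recovered totals, more than once. Transcripts that repeated the reads of another transcript of their gene in all 6 libraries occurred in 92 tested genes (0.606%) and held 0.128 to 0.156% of reads. Sharing that left unequal counts would not show in this check. Reads shared between near-identical genes, overlapping genes or antisense partners could not be separated. Cytosolic ribosomal RNA held 1.04 to 1.63% of reads, and the 10 most abundant genes held 4.71 to 5.22%.

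The choice of test depended on the unit. For size-factor-normalized values it was limma-trend (limma 3.58.1 in R 4.3.3) on log2(normalized count + 1), for the 15173 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are therefore on the log2(value + 1) scale, which understates changes of low genes. Log2 fold changes are shHBO1 minus shCTRL. The knockdown target KAT7 also had an exact two-sided permutation test, for which 3 against 3 libraries cannot give a p under 0.1. The 33 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry; 32 had at least 5 tested members. The remaining list, of 13 mitochondrially encoded mRNAs, was not analysed here.

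The design, the lists, the alternatives and the rule for naming genes were set before the data were examined. The rule named KAT7 and the HBO1 complex subunits, up to 12 genes in each direction past the threshold with a mean of at least 50 and no overlap between groups, and the 4 members of each list with the smallest p in the test without a block. Only KAT7 passed the gene-level part of it. Genes outside the rule are identified as chosen after their values were seen. A few genes that the rule or the tests would name are not reported here; counts and lists include them.

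Libraries with the same replicate number were checked for shared deviations from their group means. The correlations across genes were 0.32, 0.19 and 0.48 for numbers 1, 2 and 3. All exceeded 0.1, the limit set beforehand, so the numbers were treated as pairing the libraries, although the labels name no shared day or batch. The check is a weak test of pairing, because the deviations within a group of 3 cancel out. An outlying library in each group that shared a number without any pairing could also give positive correlations. Library shCTRL 2 correlated slightly better with shHBO1 1 (0.21) than with its own number. A fit with the replicate number as a block is reported beside the fit without it wherever it changed a call. The first principal component held 44.4% of the variance and set the number 3 libraries of both groups apart from the other libraries.

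Replicates within a group differed far beyond sampling noise, at 12.8 to 71.0 chi-square per degree of freedom between pairs of libraries. No library was therefore treated as a repeat of another, which does not show that the libraries came from separate cultures. The fits were tested on simulated data in 5 runs drawn from the means, spreads and totals of these libraries, with 200 of 15173 genes changed, all of them with a mean of at least 50. Without the block, 31.6% of 1.5-fold, 80.6% of 2-fold and 97.3% of 4-fold changes were recovered, and 6.57% of calls were false. With the block these shares were 82.4%, 95.8% and 100%, and 10.4% of calls were false, above the nominal 5%. False calls averaged 9.8 per run without the block and 21.6 with it, in runs that held 200 changed genes.

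Alternatives covered each library left out in turn, quantile normalization and median centring, no filter on low values, other pseudocounts (0.5 and 5), limma without the trend, DESeq2 1.42.0, thinning to the smallest library, and other thresholds. After the data were seen, these were added: edgeR 4.0.16 quasi-likelihood tests on the recovered reads, blocked DESeq2, a mean of at least 50, transcript-level tests, removal of both number 3 libraries, and a correction for GC content and length in the blocked fit. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.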

Results

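RNA-seq of UWB1.289 ovarian carcinoma cells compared 3 libraries with knockdown of the acetyltransferase HBO1 (shHBO1) with 3 control hairpin libraries (shCTRL). The recovered reads numbered 36081229, 39908703 and 35940400 in shCTRL replicates 1, 2 and 3, and 39716678, 37209917 and 37521281 in shHBO1 replicates 1, 2 and 3. Between 17647 and 17999 named genes had at least 1 read in a library, and 15173 genes were tested. Values are normalized counts per gene, given as mean ± SD with n = 3 per group.

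KAT7, the gene for HBO1, fell to 23.9% of its control level in the shHBO1 libraries. Its mean was 3707 ± 214 normalized counts in shCTRL and 888 ± 113 in shHBO1. The 3 control values were 3616, 3952 and 3554, and the 3 knockdown values were 1008, 872 and 784. The log2 fold change was −2.07 (SE 0.11, 95% confidence interval −2.32 to −1.82, limma adjusted p = 0.00123), a 4.19-fold lower level. The exact permutation test gave p = 0.1, the smallest that 3 against 3 allows. Within the numbered pairs, KAT7 was at 27.9%, 22.1% and 22.0% of its control. Among its 6 deposited transcripts, NM_007067 was the most abundant, at 2409 ± 241 in shCTRL and 647 ± 14 in shHBO1. NM_001199155 averaged 1171 ± 207 in shCTRL and 169 ± 85.1 in shHBO1.

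**Figure D1:**
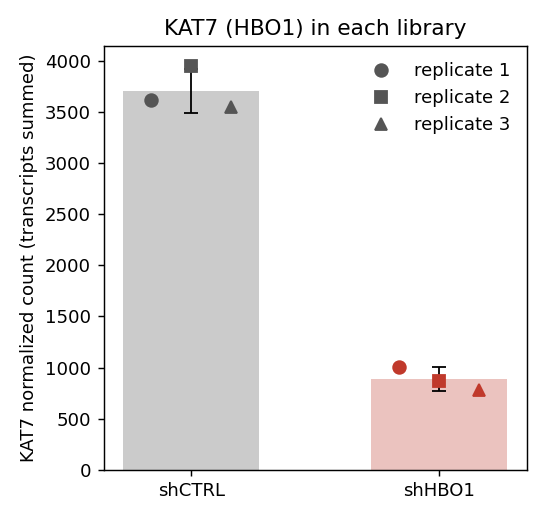
KAT7 normalized count (vertical axis, transcripts summed) in each library of the shCTRL and shHBO1 groups; bars are group means, error bars are SD with n = 3, and marker shapes give the replicate number. The 3 shHBO1 values lie between 784 and 1008 and the 3 shCTRL values between 3554 and 3952.

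The first question was which genes differed between the shHBO1 and shCTRL libraries. Because the number of hairpins is not given, other effects of a hairpin cannot be told apart from loss of HBO1. KAT7 was the only gene of 15173 past an adjusted p of 0.05 in the limma fit of the 6 libraries without a block. A further set of genes passed once the replicate number was a block: the immediate-early transcription factors EGR1 and FOS, the lipid desaturases FADS2 and SCD, the complement component C3 and the copper carrier CP (ceruloplasmin) fell, and the mesenchymal filament VIM and the matrix protease MMP2 rose. In total 19 genes passed with the block, 6 of them higher and 13 lower, and edgeR with the block called the same 19. Other blocked settings differed: DESeq2 called 147 genes, the correction for GC content and length 36, and the transcript-level test 0. The blocked fit without the number 3 libraries called 2315, but it rests on 2 pairs and has 1 residual degree of freedom. The fit without the block had 538 genes at an unadjusted p under 0.05, 263 higher and 275 lower. On the recovered reads without a block, edgeR called 1 gene and DESeq2 called 18, of which 9 were among the 19.

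Only KAT7, EGR1 and CP reached a 2-fold change with the block. EGR1 averaged 2691 ± 2059 in shCTRL and 1168 ± 944 in shHBO1, a log2 fold change of −1.14 (blocked SE 0.13, blocked limma adjusted p = 0.0301). CP averaged 379 ± 183 and 179 ± 69.7, a log2 fold change of −1.04 (blocked SE 0.12, blocked adjusted p = 0.0326). FOS had a log2 fold change of −0.93 (blocked SE 0.098, blocked adjusted p = 0.0284). Other genes that fell with the block were PCID2 (−0.86), PLAT (−0.72), which encodes tissue plasminogen activator, MAL (−0.71), MELTF (−0.55), ZHX2 (−0.51) and C3 (−0.51). Genes that rose with the block included FAM43A (+0.73), the forkhead factor FOXQ1 (+0.70), MMP2 (+0.58), VIM (+0.49) and the activin inhibitor FST (+0.48). Their blocked adjusted p-values lay between 0.0180 (MAL) and 0.0458 (FOXQ1). Apart from KAT7, FADS2, CP, VIM and MMP2, these genes were chosen after their values were seen.

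Of the 19 genes, 10 also differed between replicate numbers: MAL, FADS2, SCD, MMP2, FOS, EGR1, CP, MELTF, FST and DHCR7. In 9 of these 10, all but FST, the change in shHBO1 had the sign of the difference between number 3 and number 1. The other 9, among them KAT7, PCID2, C3, FAM43A, ZHX2, VIM, PLAT and FOXQ1, did not pass for such a difference, and DESeq2 without the block called all 9. C3 averaged 3612 ± 163 in shCTRL and 2539 ± 105 in shHBO1, and PCID2 averaged 1418 ± 217 and 778 ± 53.7. In 11 of the 19 genes the 3 shHBO1 values lay entirely on 1 side of the 3 shCTRL values. Over all tested genes 8.93% were separated in this way, where chance gives 10%.

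**Figure D2:**
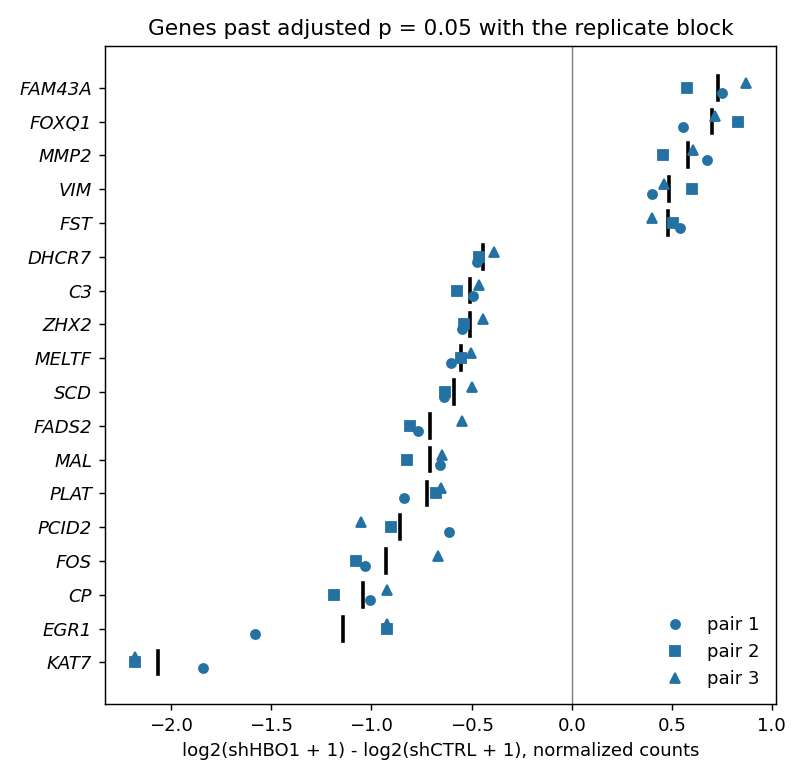
Log2 fold change (horizontal axis, shHBO1 minus shCTRL, log2(normalized count + 1)) of 18 of the 19 genes past an adjusted p of 0.05 with the replicate block; points are the 3 numbered pairs and bars are their mean. Each gene plotted has the same sign in all 3 pairs, and KAT7 has the lowest mean at −2.07.

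Genes of cholesterol and lipid synthesis, most of them targets of the SREBP transcription factors, were lower as a group in shHBO1. The median log2 fold change of the 30 tested genes was −0.31, and 29 of the 30 estimates were below 0. The list passed in limma's camera test with the preset correlation (adjusted p = 0.00116) and lost the call when the correlation was estimated (adjusted p = 0.985 with an estimated correlation). At the preset correlation, every other split of the libraries into 3 and 3 called at least as many lists. A camera call for this or a later list therefore does not by itself set shHBO1 apart. The median of the lipid list was −0.48, −0.39 and −0.15 in pairs 1, 2 and 3. Without the block 0 members fell over all genes and 0 when adjusted over the list alone. With the block FADS2 (−0.71), the fatty acid desaturase SCD (−0.59) and the cholesterol synthesis enzyme DHCR7 (−0.44) fell over all genes, and 24 members fell when adjusted over the list alone. SCD and DHCR7 were chosen after their values were seen. FADS2 averaged 11917 ± 6231 in shCTRL and 7144 ± 3416 in shHBO1. Log2 fold changes were −0.28 for FADS1 and −0.26 for EBP.

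The same lipid genes differed between replicate numbers. In 28 of the 30 members the difference between numbers passed, and the median member was lower by −1.41 on the log2 scale in number 3 than in number 1. The mean log2 level of the list was 12.80, 12.22 and 11.28 in shCTRL replicates 1, 2 and 3, and 12.33, 11.80 and 11.13 in the shHBO1 replicates. FOS values were 3650, 3064 and 131 in shCTRL and 1784, 1454 and 82.0 in shHBO1, in the same order. The list's call ended without shCTRL replicate 1 (median −0.0028, adjusted p = 0.994, test direction up) and without shHBO1 replicate 3 (median −0.0026, adjusted p = 0.855). With the block the list's adjusted p = 0.756 with an estimated correlation.

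**Figure D3:**
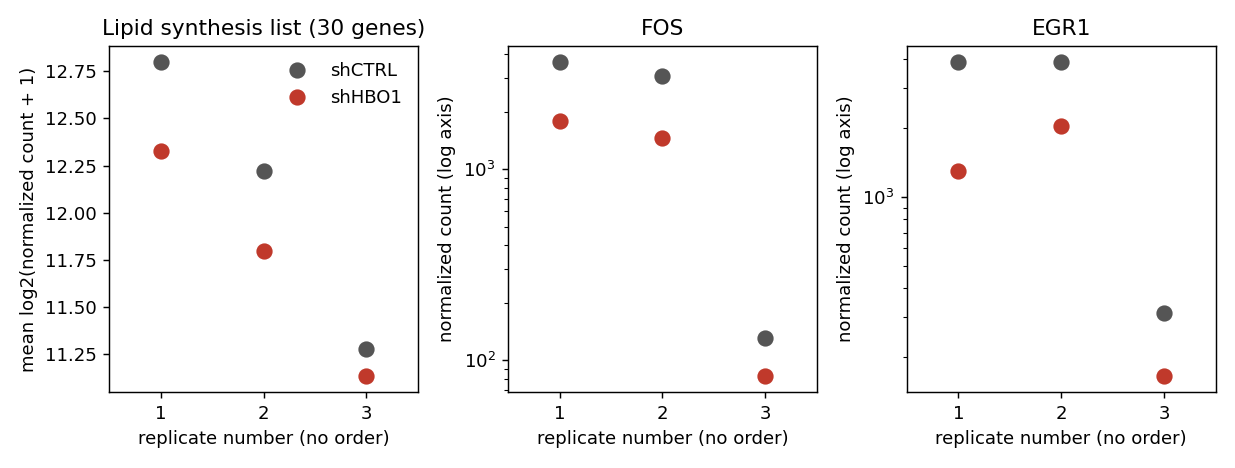
Mean log2(normalized count + 1) of the 30 lipid synthesis genes, and the FOS and EGR1 normalized counts on a log axis, against replicate number for shCTRL and shHBO1 libraries; each point is 1 library and the numbers have no order. In each panel the shHBO1 point lies below the shCTRL point of the same number, and the number 3 libraries have the lowest values.

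Mesenchymal and extracellular matrix genes were higher as a group in shHBO1. The median log2 fold change of the 31 tested genes was 0.19, and 24 estimates were above 0 (camera adjusted p = 0.00321; adjusted p = 0.985 with an estimated correlation). VIM rose when adjusted over the list alone, as 1 of 31 members, from 17105 ± 296 in shCTRL to 24053 ± 2147 in shHBO1, and 0 members rose over all genes without the block. With the block VIM and MMP2 rose over all genes, and 7 members rose when adjusted over the list alone. MMP2 averaged 7393 ± 1367 in shCTRL and 11064 ± 2167 in shHBO1. The actin-binding tropomyosin TPM2 had a log2 fold change of 0.26 (SE 0.076), and the collagen cross-linking enzyme LOX had 0.28 (SE 0.11). In this list 13 members differed between replicate numbers, with a median of 0.42 between number 3 and number 1. The call ended without shCTRL replicate 1 (median 0.090, adjusted p = 0.125) and without shHBO1 replicate 3 (median 0.12, adjusted p = 0.308). With the block the list had adjusted p = 0.756 with an estimated correlation.

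Related signalling targets were tested beside this list. The 22 YAP/TEAD and TGF-beta targets had a median log2 fold change of 0.089 and 18 estimates above 0, and did not pass without the block (camera adjusted p = 0.122). With the block the list passed (adjusted p = 0.00315; adjusted p = 0.756 with an estimated correlation), with 3 members higher and 1 lower when adjusted over the list alone. Among them ANKRD1 had a log2 fold change of 0.43, SKIL had 0.30 and the EGF receptor ligand AREG had −0.48. In this list 10 of the 22 members differed between replicate numbers, with a median of 0.19 between number 3 and number 1. The 23 WNT and MYC targets had a median of 0.042 and passed with the block (adjusted p = 0.0478; adjusted p = 0.987 with an estimated correlation) and not without it (adjusted p = 0.163). Their median was 0.23, 0.20 and −0.17 in pairs 1, 2 and 3, and 9 of the 23 differed between replicate numbers, with a median of 0.37 between number 3 and number 1. The WNT inhibitor DKK1 had a log2 fold change of 0.60 and was its only member past the threshold when adjusted over the list alone with the block. The 31 epithelial genes had a median of −0.050 (adjusted p = 0.287), and CD24 (0.58) rose with the block when adjusted over the list alone.

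Antigen presentation genes were slightly lower as a group in shHBO1. The median log2 fold change of the 18 tested genes was −0.11, and 16 estimates were below 0 (camera adjusted p = 0.00116; adjusted p = 0.566 with an estimated correlation). HLA-C averaged 6789 ± 569 in shCTRL and 5616 ± 272 in shHBO1, a log2 fold change of −0.27. It was the only member to fall when adjusted over the list alone with the block, and 0 members fell without the block. The peptide-loading protein TAPBP had −0.28, HLA-B had −0.14 and the chaperone CALR had −0.17. Reads shared between the HLA class I genes could not be separated. The call ended without shCTRL replicate 3 (median −0.061, adjusted p = 0.0629), and with the block the list had adjusted p = 0.756 with an estimated correlation. The 37 interferon-stimulated genes had a median of −0.091 and did not pass (adjusted p = 0.388), with SAMD9 at 0.36 and ISG15 at −0.15.

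Among 21 genes of the ovarian serous and Mullerian lineage, WFDC2, which encodes the tumour marker HE4, fell from 1495 ± 101 to 1112 ± 58.1 normalized counts. Its log2 fold change of −0.43 passed when adjusted over the list alone and not over all genes. The list had a median of −0.10 and 13 estimates below 0. It passed with the block (camera adjusted p = 0.0139; adjusted p = 0.955 with an estimated correlation) and not without it (adjusted p = 0.122). With the block CP fell over all genes. When adjusted over the list alone with the block, 7 members fell, among them FOLR1 (−0.84), mesothelin MSLN (−0.37) and, chosen after their values were seen, the mucins MUC1 (−0.60) and MUC16 (−0.39). MECOM (0.39) rose by the same criterion. In 8 of the 21 members the replicate numbers differed, with a list median of −0.39 between number 3 and number 1.

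Genes tied to the known roles of HBO1 in chromatin and replication did not pass, KAT7 apart. The other subunits of the HBO1 complexes had log2 fold changes from −0.16 for ING5 to 0.23 for BRPF3. BRPF1 had 0.098, BRD1 had 0.090, JADE1 had −0.046, JADE2 had 0.081, JADE3 had −0.027, ING4 had −0.11 and MEAF6 had −0.064. Of 13 other lysine acetyltransferases 0 passed over all genes or when adjusted over the list alone, and KAT2B (0.33), KAT8 (−0.20), EP300 (0.18) and CREBBP (0.18) had the smallest p-values. The 28 replication licensing and origin factors had a median of −0.019 and 0 passed by either adjustment. GINS1 had −0.15, CDC45 had −0.11 and the licensing factor CDT1 had −0.092, and of the 28 estimates 19 were below 0 and 9 above. The lowest bound of any member's 95% confidence interval in this list was −0.43. Larger decreases lay outside the interval of each of the 28 genes, and smaller ones were not excluded.

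The cell cycle and DNA repair lists did not pass either. The 38 G1/S genes had a median of −0.0046 (camera adjusted p = 0.748), with thymidylate synthase TYMS at −0.28. The 41 G2/M genes had a median of 0.0082 (adjusted p = 0.748), with the mitotic survival factor BIRC5 at 0.18. The 31 homologous recombination and Fanconi genes had a median of 0.024 (adjusted p = 0.577), with BRCA2 at 0.33 and CHEK2 at −0.23. The 21 replication-dependent histone genes had a median of 0.21 (adjusted p = 0.197) at a typical mean of only 25.0 normalized counts. Individual histone genes share near-identical sequence and are uncertain. The 28 p53 targets had a median of −0.025 (adjusted p = 0.868), with FAS at −0.25, and 15 estimates were below 0 and 13 above. The 27 apoptosis regulators had a median of 0.023 (adjusted p = 0.981). In these lists 0 members passed over all genes or when adjusted over the list alone.

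Stress, developmental and housekeeping genes had small differences, and 0 of their members passed by either adjustment. Medians were 0.026 for 30 ATF4 and unfolded protein response genes, 0.062 for 20 heat shock and NRF2 genes, and 0.084 for 27 HOX and developmental regulators, with HOXB9 at 0.75 (SE 0.37). The 57 cytosolic ribosomal protein genes had a median of −0.037 (camera adjusted p = 0.122), the 42 nuclear-encoded respiratory chain genes −0.012, and the 28 housekeeping genes −0.020. The 12 nuclear-retained and structural RNAs, a sign of RNA quality, had −0.033. Markers of other cell types did not pass as lists, with camera adjusted p = 0.418 for 10 leukocyte genes, 0.981 for 11 fibroblast and endothelial genes, 0.639 for 7 mesothelial genes and 0.981 for 9 neural genes. Among them CD14, a gene of low counts, averaged 38.9 ± 0.618 in shCTRL and 18.6 ± 5.21 in shHBO1. It did not pass over all genes or when adjusted over its list alone, with or without the block. With the block CDH5 (−0.46), PDPN (−0.48) and MSLN fell and MFAP5 (0.93) rose when adjusted over their lists alone. The ATF4, apoptosis, steroid receptor, fibroblast, mesothelial and neural lists had medians, means or test directions that differed in sign.

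**Figure D4:**
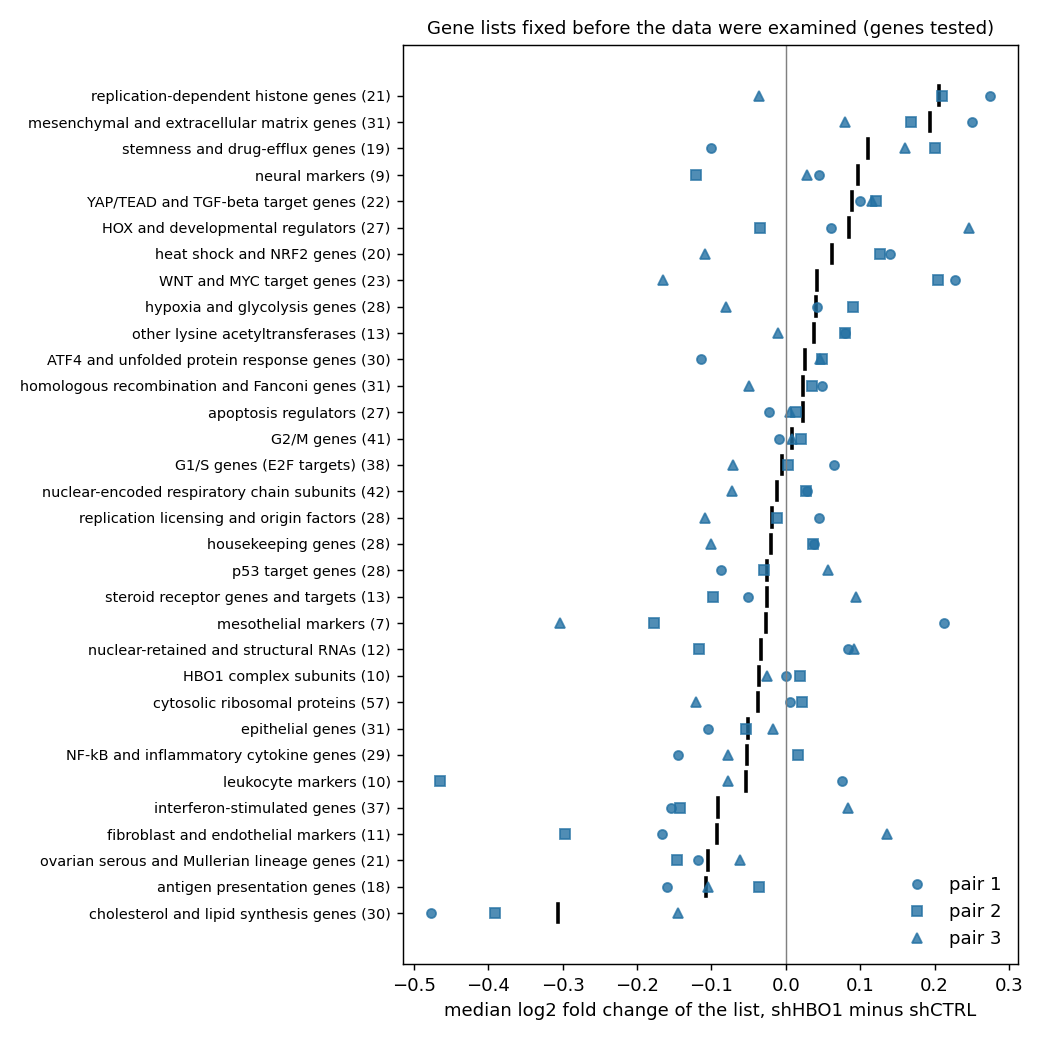
Median log2 fold change (horizontal axis, shHBO1 minus shCTRL) of each of the 32 tested gene lists, with the number of tested genes in brackets; bars are medians over the fitted fold changes and points are medians in the 3 numbered pairs. The lipid synthesis list has the lowest median at −0.31, and the mesenchymal and matrix list lies at 0.19.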

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

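The settings with edgeR, blocked DESeq2, a mean of at least 50, transcripts, the pair numbered 3 left out, blocked quantile normalization, the GC content and length correction, and a blocked estimated correlation or fry were chosen after seeing the data. KAT7 passed in each of the 25 gene-level alternatives that tested it, with log2 fold changes from −2.16 to −1.98. At transcript level its most abundant transcript passed without the block (limma adjusted p = 0.0379) and not with it (limma adjusted p = 0.635). Without the replicate block, 1 gene passed with each library left out in turn, and with the other scalings, filters, pseudocounts, thresholds and edgeR. DESeq2 called 18. With the replicate block 19 genes passed, 3 of them at 2-fold, and 6 lists. Blocked edgeR called 19 genes, 4 at 2-fold, and 7 lists, and blocked DESeq2 147 genes, 7 at 2-fold. Blocked quantile normalization gave 21 genes, 3 at 2-fold, and 6 lists. The blocked correction for GC content and length gave 36 genes, 6 at 2-fold, and 7 lists. On blocked transcripts 0 genes passed and 0 at 2-fold, with 1854 transcripts at an unadjusted p under 0.05. The cause of these differences was not tested. Without the number 3 pair, 9 lists passed with or without the block, and limma called 1 gene without the block and 2315 with it, 124 of these at 2-fold. The blocked fit had 1 residual degree of freedom, and it called 0 genes with the libraries swapped in 1 of the 2 pairs. That swap turns a difference shared by both pairs into residual spread. The 0 was thus nearly fixed in advance and does not test the calls.

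With each library left out in turn the number of lists ran from 4 to 10, against 3: it was 7 without shCTRL 2, 8 without shCTRL 3, 5 without shHBO1 1 and 10 without shHBO1 2. Camera with an estimated correlation and the directional test of fry called 0 lists, with or without the block. These tests leave the medians as they are, at −0.31 (lipid), 0.19 (mesenchymal) and −0.11 (antigen presentation), and their adjusted p ran from 0.268 to 0.985. The mixed test of fry, for changes in either direction, passed for 2 lists without the block and 9 with it. The 2 were the HBO1 complex subunits, which include the target KAT7 (fry mixed adjusted p = 0.000323), and the stemness genes (fry mixed adjusted p = 5.54e-06). The 9 were these and the mesenchymal, YAP/TEAD and TGF-beta, ovarian, NF-kB, histone, leukocyte and mesothelial lists. Left-out libraries moved the lipid median between −0.75 and −0.0026, with −0.0028 and a reversed test direction without shCTRL 1. The mesenchymal median ran from 0.090 (without shCTRL 1) to 0.26, with 0.12 without shHBO1 3. The antigen presentation median ran from −0.13 to −0.061 (without shCTRL 3). The G2/M median ran from −0.062 to 0.062, and the list passed at −0.059 (adjusted p = 0.0256) without shHBO1 2, and above 0 without shCTRL 2 or shHBO1 3. Over all alternatives the adjusted p ran from 1.1e-40 to 0.994 for the lipid list, 2.14e-08 to 0.985 for the mesenchymal, 0.000315 to 0.756 for the antigen presentation and 0.00639 to 0.999 for the G2/M list. The cause was not tested. In limma and camera the block changed no other call of a gene or list, nor another count within a list. Thinning to the smallest library left 1 gene and 3 lists.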

Other observations

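The count of splits giving as many genes without the block, and the comparison of lipid and other genes pair by pair, were tests chosen only after the result was seen. The correction for GC content and length was added after the data were seen. Of the genes named in this part, ICAM1, ANGPTL4, SGK1, DUSP1, EGR1, HMGCS1, INSIG1 and GREM1 were chosen after their values were seen.

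Inflammatory and stemness genes held a few further differences. In the list of 29 NF-kB and inflammatory cytokine genes, with a median log2 fold change of −0.053 (camera adjusted p = 0.264), the chemokine CCL2 (−0.89) and the adhesion molecule ICAM1 (−0.34) fell with the block when adjusted over the list alone. IL1B had −1.48 (SE 0.40) and did not pass by either adjustment. Of the 29 estimates 18 were below 0 and 11 above, and 10 members differed between replicate numbers. Among 19 stemness and drug-efflux genes, with a median of 0.11 (adjusted p = 0.423), the Polycomb subunit BMI1 (0.30) and NOTCH1 (0.34) rose with the block when adjusted over the list alone, and HEY1 had 0.79 (SE 0.21). Among 13 steroid receptor genes and targets, with a median of −0.026 (adjusted p = 0.767), GATA3 (−0.75) and DUSP1 (−0.52) fell, and GREB1 (0.53) and SGK1 (0.42) rose by the same criterion. In the 28 hypoxia and glycolysis genes, with a median of 0.041 (adjusted p = 0.856), PFKL (−0.26) and EGLN3 (−0.61) fell and ANGPTL4 (0.83) rose by that criterion too. Without the block 0 genes of these 4 lists passed by either adjustment in limma.

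In the blocked fit of all 6 libraries, more genes passed for a difference between replicate numbers than the 19 between shHBO1 and shCTRL. The counts come from unlike tests, a joint F test over all replicate numbers and a t test of the group difference. In the blocked limma t test, 1716 genes had an unadjusted p under 0.05 between shHBO1 and shCTRL. Without the number 3 pair, the blocked fit called 2315 genes between shHBO1 and shCTRL, so this ranking is given for the 6 libraries only. Those 2315 calls were not told apart from a shift of the shHBO1 libraries along the difference between replicate numbers. In limma 1469 genes (9.68%) differed between the numbers, 735 higher and 734 lower in number 3 than in number 1. EGR1 and DUSP1 were low in both number 3 libraries. EGR1 was at 314 in shCTRL and 165 in shHBO1, against 3892 and 1300 in the number 1 libraries. DUSP1 was at 425 and 371, against 1931 and 1141. HMGCS1 and INSIG1 of the lipid list were low in the same libraries, with HMGCS1 at 3112 and 2973 against 23181 and 13688, and INSIG1 at 1437 and 1405 against 10229 and 6733. GREM1, a BMP antagonist, was higher in number 3, at 2346 and 2297 against 482 and 591, as was ANGPTL4, at 908 and 1218 against 72.1 and 153. The mitochondrial ribosomal RNA share was 0.207% and 0.221% in number 3, against 0.596% and 0.395% in number 1.

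Few genes passed in the fit without the block. Of the 10 splits of the 6 libraries, 2 gave as many genes, with 1 gene in the real split and at most 1 in any other. With the block, among the 4 splits that part all pairs, 1 gave as many genes, the real one, with 19 genes against at most 0 elsewhere. Each other split with the block swaps the libraries of 1 pair, which turns a difference shared by the pairs into residual spread. The 0 elsewhere was thus nearly fixed in advance and does not test the 19 calls. Both sets of splits are too few for a share under 0.05. Too few reads or libraries for 2-fold changes is argued against by simulation, in which 80.6% of 2-fold changes passed without the block, while 1.5-fold changes passed in 31.6% and may be missing; with 200 changed genes the simulated adjustment was also milder than with 1.

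The lipid synthesis list was lower in shHBO1. All 10 splits gave at least as many lists as the real 3, the highest other gave 14, and the 10 splits are too few for a share under 0.05; with the block the 3 other splits called 7 to 11 lists against 6, all at the preset correlation. A bias of GC content and length is argued against, because the median was −0.32 after the correction with the block (camera adjusted p = 1.57e-26 at the preset correlation, in a range of 1.1e-40 to 0.994 over all alternatives); the blocked list without that correction had adjusted p = 0.756 with an estimated correlation. A candidate explanation that stays open is a shift of the shHBO1 libraries along the difference between replicate numbers. The 200 genes outside the list that differed most between numbers shifted by 0.174 (SE 0.070) of their number 3 against 1 difference. The lipid genes shifted by 0.253 (SE 0.082) of theirs. The shares lay within 2 SE of each other, the outcome that the rule set before this test expected of such a shift. In a comparison chosen afterwards, the lipid share was the higher in each of the 3 pairs, by 0.078 on average (SE 0.013). Choosing the 200 genes for a large difference may itself lower their share, so this excess does not decide against the shift. An effect of HBO1 on these genes also stays open, and the sign of that shift was shown by 77.2%, 74.4% and 41.1% of the other 1441 differing genes in pairs 1, 2 and 3, where the lipid medians were −0.48, −0.39 and −0.15.

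The difference between replicate numbers itself was weighed against technical explanations, and no biological explanation was tested because the design gives none. Depth was examined by thinning, and 1544 genes differed after it and 1469 before. The recovered totals ran only from 35940400 to 39908703 reads, so thinning changed little and was a weak test of depth. A GC content and length bias is argued against as the whole cause, since 1695 genes differed after the correction and 1551 before, among the genes with known GC content. A shared culture or preparation day for each number may have produced it, and stays open because the labels give none.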
